A study of Neurospora crassa OR74A with 26 samples.

How the data were processed

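The analysis uses the deposited FPKM per transcript, which the authors computed with Cufflinks 0.9.3 after alignment with TopHat, per the submitters' processing notes. The deposited files also list a Cufflinks coverage signal and transcript lengths in bases, per the file headers. The coverage and the lengths served only to recover the number of reads. The sample titles call the deleted genes cdr1 and cdr2; they were read as clr-1 and clr-2 because the genotype labels give NCU07705 and NCU08042. The authors' cluster file holds a clustering weight, a score, and only its gene IDs were used. The authors' DESeq tables list means of counts divided by size factors, a score, with a fold ratio and p values, and the authors' edgeR tables list a log2 fold change and p values. The calls rest on FPKM and not on a count model; numbers of reads recovered from the coverage entered only the voom alternative and the depth checks. The genome build is not stated. The 9907 transcripts were summed to 9733 genes, 164 of which have more than 1 transcript. The reference table names 8914 of the genes and gives 1093 a symbol of their own; by its coordinates, 1-based, cbh-1 lies on supercontig 4 at 4311049 to 4313881. All sample columns were used (0 unused). No pair of libraries is identical.

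The 75th percentile of FPKM lies between 231 and 277 in all libraries, as upper-quartile scaling would give, though no scaling is stated, and no further scaling was applied. Coverage times effective length divided by read length came out as a whole number of reads for 87.5% to 93.0% of the transcripts under 200 reads (tolerance 0.02), and gave 11.8 M to 110.6 M reads per library. Values of 0 start at about 10 reads, so listed at 0 means too few reads to be listed; 718 to 2346 transcripts per library are at 0. Of 4465 genes with a median of at least 100 FPKM, 30 are at 0 in some library, so a single 0 can also be a failed estimate. Pearson r of log2 values between replicates lies between 0.938 and 0.994 over 15 pairs. In the Avicel and sucrose triplicates, replicate 1 has reads of 36 or 40 bases and the others 50. Pairs with replicate 1 there have r of 0.938 to 0.976, and pairs of replicates 2 and 3 have 0.992 to 0.994. Much of the spread in these groups thus lies between replicate 1 and the others.

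Values were log2(FPKM + 1). Genes with a mean of at least 1 FPKM over all libraries were tested, 8629 in all. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 26 libraries in 16 groups, 5 with 3 libraries and 11 with 1. The residual degrees of freedom are 10, the prior adds 3.35, and the median residual SD is 0.391. eBayes used a trend, tests are two-sided, and adjusted p is Benjamini-Hochberg over the tested genes of 1 comparison, called under 0.05. The spread comes from wild-type triplicates only. A single deletion library is assumed to vary in the same way, and no deletion group has replicates to check that. Between the deletion strains on Avicel at 4 h, a share far under 0.05 of the tested genes had an unadjusted p under 0.05. That is fewer than no difference would give, so the wild-type spread may be too wide for these libraries. There are 14 comparisons: Avicel against sucrose at 4 h and 1 h, Avicel against no carbon and no carbon against sucrose at 4 h, the difference of the Avicel responses, each deletion against wild type on Avicel at 4 h and 1 h and on sucrose at 4 h, each deletion's change in the Avicel response, and the deletion strains against each other. The means and SD printed are of FPKM, and the changes and SE of log2 values.

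The lists were fixed by gene ID before the data were examined: cellulases, LPMO and cellobiose dehydrogenase, hemicellulases, sugar transporters, regulators, pectin degradation, starch degradation, pentose metabolism, glycolysis, glyoxylate and gluconeogenesis, ER folding and secretion, conidia and conidiation markers, light and clock, qa cluster and housekeeping. To these 15 the authors' clusters were added, 212 genes of which 211 were tested. Another 7 lists, defined by product text, were left out because the files hold no product text. limma camera tested each list with at least 3 tested members against all other genes with a preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation is an alternative to it. fry, also run, asks another question, whether the genes of a list changed in a common direction, without setting them against other genes. Members were also counted as higher, lower or not passing, and once more with p adjusted over the list alone.

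The genes named were set by a rule: clr-1 and clr-2, the 10 largest rises and 10 largest falls among called genes with at least 10 FPKM in the higher group and no overlap between libraries, up to 4 members of each list with the highest level, and all regulators. The text gives a selection of these genes.

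Replicate numbers may mark shared cultures, but on Avicel and sucrose replicate 1 also has reads of 36 or 40 bases and the others 50. Deviations from group means of libraries with the same number correlate at 0.12 to 0.18 between Avicel and sucrose at 4 h and at 0.18 to 0.28 at 1 h, and 5 of 6 libraries in each comparison are closest to their own number. With the number as a block, 5208 and 5485 genes were called there in place of 5043 and 5348. For replicate 1 a shared culture cannot be told apart from read length. Among replicates 2 and 3 at 1 h, same numbers correlate at 0.18 and 0.24 and different numbers at 0.17 and 0.19. At 4 h these are 0.12 and 0.18 against 0.06 and 0.16.

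A self-test ran the same code on simulated values, normal around each gene mean with the fitted spread, in which 50 genes above 10 FPKM were changed at each fold, up or down. For Avicel against sucrose at 4 h it recovered 40%, 80%, 98% and 100% of genes changed 2-, 4-, 16- and 64-fold, with 12 false calls. For the clr-1 deletion against wild type on Avicel at 4 h it recovered 12%, 66%, 96% and 96% (4 false calls), for the clr-2 deletion 12%, 58%, 92% and 98% (4), for the 4 h against 1 h response 10%, 74%, 98% and 100% (9) and for the clr-1 change in the response 0%, 34%, 82% and 90% (5). An absent call in the deletion strains therefore leaves changes of 2-fold largely untested. It does not exclude changes of 4-fold either, of which 66% and 58% were recovered for the clr-1 and clr-2 deletions. For the clr-1 change in the response most 4-fold changes were missed (34% recovered), and some of 16-fold and 64-fold (82% and 90% recovered). A raised list was found in all 5 settings and an unchanged list in none.

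The alternatives set beforehand are pseudocounts of 0.1 and 10, no filter and a filter of 10 FPKM, rescaling to the median of gene ratios, the replicate block, no trend, only the compared libraries, each library left out, and the list tests above. Chosen after seeing the data were the fit without the 36- and 40-base libraries, a read-length covariate and voom on the recovered reads. In the authors' tables the columns named for the media run opposite to FPKM: the correlation of their log2 ratio with the FPKM change is -0.968 for sucrose and -0.949 for no carbon, and 4586 of 4591 and 1183 of 1212 genes with at least a 2-fold change by FPKM have the opposite sign. The fold column of these tables was read as Avicel over the other medium and the log2 fold of the edgeR tables of the authors with its sign turned, both because FPKM then match, so the shared direction is partly set by that choice.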

Results

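Neurospora crassa is a filamentous fungus that lives on plant cell walls and secretes enzymes that degrade cellulose. In this experiment cultures grown for 16 h in sucrose were washed and moved to Avicel, which is crystalline cellulose, to fresh sucrose or to medium without a carbon source. RNA was sequenced from 26 libraries: 18 of wild type and 4 of each of 2 strains lacking the transcription factor gene clr-1 or clr-2. Wild type has 3 biological replicates on Avicel and on sucrose at 1 h and 4 h and without carbon at 4 h. Every deletion group is 1 library. All values are the deposited FPKM, summed to genes. Log2 changes are differences of mean log2(FPKM + 1), and adjusted p values come from limma, two-sided, over 8629 tested genes. A change is said to rise or fall where the adjusted p is under 0.05. Recovered reads range from 11.8 M to 110.6 M per library (M, mega). The wild-type replicate 1 libraries on Avicel and sucrose have reads of 36 or 40 bases, whereas all the no-carbon libraries have reads of 51 bases, so that a difference between these and the 50-base libraries cannot be separated from the medium.

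The first question is which genes change when cellulose replaces sucrose for 4 h. Among the largest rises were genes of cellulose and hemicellulose breakdown. The cellobiohydrolase gene cbh-1, whose enzyme releases cellobiose from chain ends, went from 32.7 ± 32.6 FPKM on sucrose to 125860 ± 53336 FPKM on Avicel (n = 3; log2 change 12.23, SE 0.50, adjusted p = 7.8e-10). The cellobiose dehydrogenase gene cdh-1, which supplies electrons to polysaccharide monooxygenases, rose by 9.64 (SE 0.29, adjusted p = 6.0e-11), and the monooxygenase gene gh61-5 by 10.79 (SE 0.43, adjusted p = 6.0e-10). The cellodextrin transporter gene cdt-1 rose by 8.60 (SE 0.49, adjusted p = 1.3e-08). The regulator genes rose as well: clr-1 from 45.6 ± 6.59 to 801.8 ± 245.3 FPKM (log2 change 4.06, SE 0.36, adjusted p = 6.3e-07), clr-2 from 2.43 ± 0.306 to 1311 ± 200.2 FPKM (8.57, SE 0.35, adjusted p = 8.5e-10) and xlr-1, a regulator of hemicellulase genes, by 6.93 (SE 0.29, adjusted p = 1.1e-09). Overall 5043 genes changed, 2958 higher and 2085 lower on Avicel, and 425 of the higher and 216 of the lower changed by at least 16-fold.

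All 12 cellulase genes, all 19 hemicellulase genes, all 13 sugar transporter genes and all 5 genes of pentose use were higher on Avicel at 4 h, also when adjusted over the list alone. Of the 14 genes for polysaccharide monooxygenases and cellobiose dehydrogenase, 11 were higher and 3 did not pass; adjusted over the list alone 12 were higher and 1 lower. As groups against all other genes (camera), cellulases (adjusted p = 1.7e-08; adjusted p = 0.042 with an estimated correlation), hemicellulases (adjusted p = 1.0e-10; adjusted p = 0.0097 with an estimated correlation) and sugar transporters (adjusted p = 5.2e-07; adjusted p = 0.042 with an estimated correlation) were higher. The pentose genes were higher at adjusted p = 0.0078, but adjusted p = 0.241 with an estimated correlation. Of the 8 genes for protein folding in the endoplasmic reticulum, 7 were higher and 1 did not pass (8 adjusted over the list alone), among them the chaperone gene grp78, which went from 3303 ± 994.6 to 13687 ± 2110 FPKM (log2 change 2.08, SE 0.42, adjusted p = 7.8e-04); the group gave adjusted p = 0.0113, and adjusted p = 0.257 with an estimated correlation. Starch degradation had 5 of 6 genes higher (camera adjusted p = 0.0093; adjusted p = 0.042 with an estimated correlation) and the regulators 5 of 6 (adjusted p = 0.0139; adjusted p = 0.13 with an estimated correlation). The pectin genes split, 3 higher and 1 lower.

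Of the 10 glycolysis genes 7 were lower on Avicel and 3 did not pass (camera adjusted p = 0.0012; adjusted p = 0.207 with an estimated correlation), with the enolase gene emp-7 falling from 30115 ± 8416 to 5695 ± 2322 FPKM (log2 change -2.44, SE 0.35, adjusted p = 4.4e-05). The largest falls included the branched-chain amino acid gene ilv-2, from 15993 ± 3487 to 132 ± 88.9 FPKM (log2 change -7.08, SE 0.43, adjusted p = 2.3e-08). Genes of the glyoxylate cycle and gluconeogenesis were mixed, with 2 higher, 1 lower and 2 not passing. Of 7 housekeeping genes 2 were lower and 5 did not pass; the elongation factor gene tef-1 fell (log2 change -1.94, adjusted p = 9.3e-04). Markers of conidia, the asexual spores, differed too: 5 of 6 were higher on Avicel (6 adjusted over the list alone; camera adjusted p = 0.0114, adjusted p = 0.241 with an estimated correlation), as were 4 of 6 light and clock genes and 1 of 6 genes of the quinic acid cluster. Of 211 genes in the authors' cluster list, 186 were higher and 25 did not pass; the study chose that list on these same samples, so the count is not independent evidence.

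**Figure D1:**
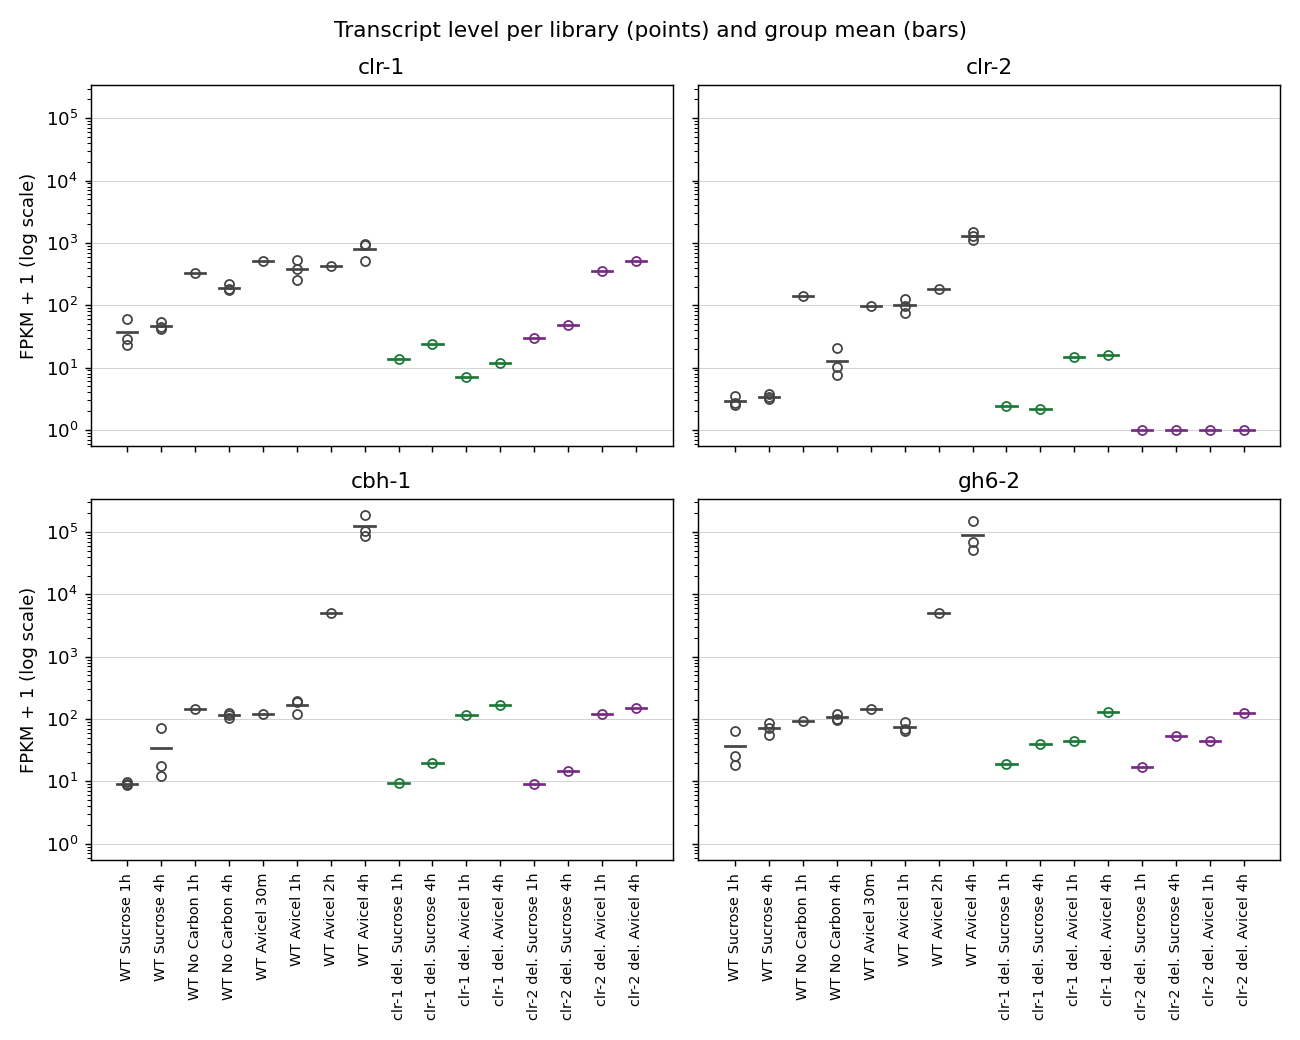
FPKM + 1 of clr-1, clr-2, cbh-1 and gh6-2 in every library. Points are libraries and bars are group means.

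Because a culture moved from sucrose to Avicel also loses its sugar, Avicel was compared with no carbon at 4 h. Cellulose degradation genes were among the largest differences. The cellobiohydrolase genes cbh-1 and gh6-2 were at 114.1 ± 9.76 and 105 ± 13.1 FPKM without carbon, and higher on Avicel by 10.02 (SE 0.50, adjusted p = 1.7e-08) and 9.59 (SE 0.43, adjusted p = 6.7e-09). The regulator clr-2 stood at 11.8 ± 6.94 FPKM without carbon (log2 change to Avicel 6.80, SE 0.35, adjusted p = 2.2e-08) and clr-1 at 190.3 ± 26.5 FPKM (2.03, SE 0.36, adjusted p = 0.0034). The xylose reductase gene xr, the entry to pentose use, rose by 7.96 (SE 0.67, adjusted p = 4.5e-06), and grp78 rose by 2.88 (SE 0.42, adjusted p = 7.8e-04). In all 465 genes changed, 316 higher and 149 lower on Avicel, with 77 higher and 0 lower by at least 16-fold; 1522 genes had an unadjusted p under 0.05 and voom called 596. The count was 300 without the no-carbon 4 h replicate 3 library, and 1136 (596 higher, 540 lower) without the 36- and 40-base libraries.

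Among the lists, 10 of 12 cellulase genes were higher on Avicel than without carbon and 2 did not pass (12 adjusted over the list alone; camera adjusted p = 3.1e-33), 16 of 19 hemicellulase genes were higher and 3 did not pass (17 alone), and 10 of 14 monooxygenase and dehydrogenase genes were higher and 4 did not pass (11 higher and 1 lower alone). With an estimated correlation camera gave the cellulases adjusted p = 4.8e-04. Endoplasmic reticulum folding genes were higher in 7 of 8 cases, and sugar transporters in 5 of 13 (7 alone). The regulators had 4 of 6 higher, the pentose genes 3 of 5 (camera adjusted p = 1.7e-05; adjusted p = 0.063 with an estimated correlation) and pectin degradation 1 of 4. No conidiation marker differed singly; as a group the markers were lower on Avicel (adjusted p = 0.0375), but adjusted p = 0.279 with an estimated correlation. Among light and clock genes 1 of 6 was lower on Avicel and 5 did not pass. Only 1 of 10 glycolysis genes and no housekeeping or quinic acid cluster gene differed. Every 51-base library is a no-carbon library, so a difference in preparation cannot be separated from the medium.

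Between no carbon and sucrose at 4 h 5456 genes differed, 3416 higher and 2040 lower without carbon. The no-carbon libraries have 51-base reads, and those with 108.3 M and 110.6 M reads are the deepest of all. They have 718 to 1002 transcripts at 0. The sucrose libraries have 40- or 50-base reads and 1645 to 2346 transcripts at 0. Low genes with too few reads are listed at 0, so depth may add to the genes higher without carbon. The counts therefore cannot be credited to starvation alone. Genes that rose include the glucose-repressed gene ccg-1, which went from 1022 ± 602 to 243040 ± 66000 FPKM (log2 change 8.12, SE 0.71, adjusted p = 5.3e-07), and the high-affinity glucose transporter gene hgt-1 from 190 ± 98.3 to 2562 ± 403 FPKM (3.91, adjusted p = 2.9e-06). The regulator xlr-1 rose by 5.15 (SE 0.29, adjusted p = 1.7e-08), clr-1 by 2.04 (SE 0.36, adjusted p = 2.5e-04) and clr-2 by 1.77 (SE 0.35, adjusted p = 6.2e-04). The cellulase gene cbh-1 rose by 2.21 (SE 0.50, adjusted p = 0.0016). Genes that fell include ilv-2 (log2 change -7.78, SE 0.43, adjusted p = 1.4e-08) and eth-1, which makes S-adenosylmethionine and went from 11614 ± 3600 to 77.3 ± 10.2 FPKM (log2 change -7.17, adjusted p = 2.7e-08).

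Without carbon 10 of 12 cellulase genes, 17 of 19 hemicellulase genes and 12 of 13 sugar transporter genes were higher than on sucrose, and 5 monooxygenase and dehydrogenase genes were higher, 4 lower and 5 did not pass. The median log2 difference of the cellulases from sucrose was 1.73 without carbon and 10.102 on Avicel. As groups (camera), hemicellulases gave adjusted p = 0.00196 (adjusted p = 0.217 with an estimated correlation) and sugar transporters adjusted p = 6.5e-04 (adjusted p = 0.217 with an estimated correlation); of 9 lists called, 0 were called with an estimated correlation. Glycolysis had 9 of 10 genes lower and 1 not passing, and the starch genes 5 of 6 higher. All 6 conidiation markers, 5 of 6 light and clock genes and 3 of 6 quinic acid cluster genes (2 adjusted over the list alone) were higher without carbon, and 4 of 7 housekeeping genes were lower. Endoplasmic reticulum folding genes went both ways, 2 higher, 4 lower and 2 not passing.

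**Figure D2:**
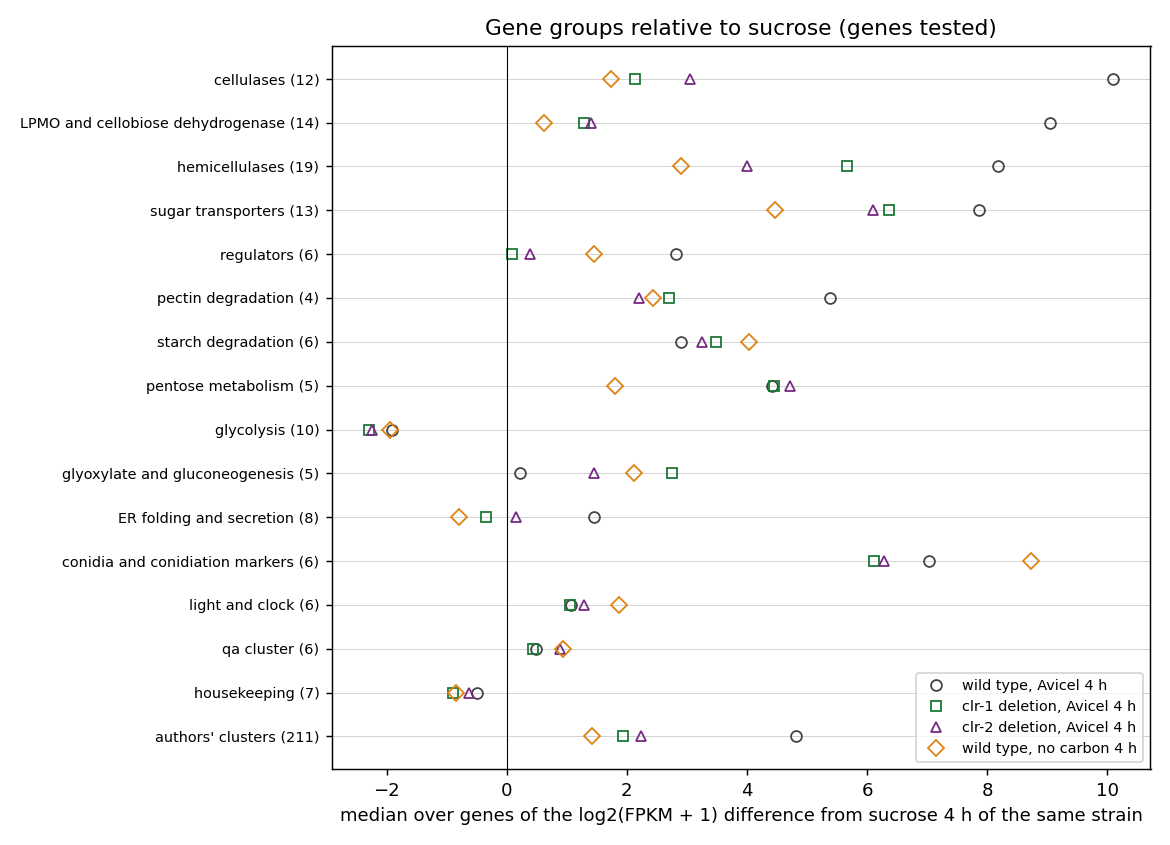
Median log2 difference from sucrose at 4 h for each gene list, in wild type on Avicel, in wild type without carbon and in the deletion strains on Avicel. Each deletion strain is set against its own sucrose library.

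Genes specific to cellulose are those higher on Avicel than in both other media at 4 h. There were 239 of them, among 2958 higher against sucrose and 316 higher against no carbon. Independent calls would share 108.32. A simulation without effects shared 0, but it calls almost no gene and so gives no baseline for lists of this size. Part of the excess may come from the shared Avicel libraries. Lower in both were 28 genes, against 36.002 for independent calls.

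Gene expression 1 h after the shift shows which parts of the response come early. Sugar transporter genes were among those that rose: hgt-1 rose from 1482 ± 585 to 63508 ± 19002 FPKM (log2 change 5.45, SE 0.41, adjusted p = 1.8e-07) and the transporter gene NCU05897 by 10.33 (SE 0.70, adjusted p = 7.6e-08). The beta-glucosidase gene gh3-3, whose enzyme splits cellobiose, rose by 8.04 (SE 0.92, adjusted p = 5.8e-06), but cbh-1 rose only to 166 ± 41.0 FPKM (4.16, SE 0.50, adjusted p = 8.6e-06). The regulators clr-1 (3.43, SE 0.36, adjusted p = 2.7e-06), clr-2 (5.08, SE 0.35, adjusted p = 8.4e-08) and xlr-1 (5.52, SE 0.29, adjusted p = 1.5e-08) rose, while vib-1, a regulator tied to carbon repression, fell (log2 change -2.86, adjusted p = 4.0e-05). In total 5348 genes changed, 3221 higher and 2127 lower. All 13 sugar transporters (camera adjusted p = 3e-06; adjusted p = 0.138 with an estimated correlation), 11 of 12 cellulases, 11 of 19 hemicellulases and 9 of 14 monooxygenase and dehydrogenase genes (10 adjusted over the list alone) were higher, and 1 of the 14 was lower. Lower too were 4 of 10 glycolysis genes (3 alone), 3 of 7 housekeeping genes (2 alone) and 1 of 4 pectin genes, whose other 3 were higher. Starch degradation (6 of 6), the quinic acid cluster (6 of 6) and glyoxylate and gluconeogenesis (4 of 5) were higher too, the last with fructose bisphosphatase, fbp-1, up from 202 ± 67.2 to 2518 ± 278 FPKM (3.69, adjusted p = 1.3e-05). Endoplasmic reticulum folding genes had 1 higher, 1 lower and 6 not passing. With the libraries rescaled to the median of gene ratios the median log2 change over all genes went from 0.34 to 0.20, while the call count was 5337.

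The difference between the Avicel response at 4 h and at 1 h was tested as an interaction, and 2684 genes differed, 1278 with a higher and 1406 with a lower log2 difference between Avicel and sucrose at 4 h than at 1 h; a gene that falls more at 4 h counts as lower. Genes of secreted enzymes were among those with a larger response at 4 h: the response of gh6-2 was larger at 4 h by 8.96 (SE 0.61, adjusted p = 9.3e-07), that of cbh-1 by 8.07 (SE 0.70, adjusted p = 1.0e-05) and that of cdh-1 by 8.09 (SE 0.41, adjusted p = 1.4e-07). The regulator clr-2 gained 3.49 (SE 0.50, adjusted p = 3.0e-04) and vib-1 gained 4.28 (SE 0.57, adjusted p = 2.0e-04). NCU05627, an early gene, was at 8297 ± 2649 FPKM on Avicel at 1 h and 228 ± 126 FPKM at 4 h, and its response was smaller at 4 h (log2 change -7.31, SE 0.88, adjusted p = 9.2e-05). The difference was higher at 4 h for 10 of 12 cellulases, 10 of 14 monooxygenase and dehydrogenase genes and 17 of 19 hemicellulases (18 adjusted over the list alone), and for 4 of 8 endoplasmic reticulum folding genes (6 alone; camera adjusted p = 0.0033, adjusted p = 0.314 with an estimated correlation). The sugar transporters were split, 4 higher, 2 lower and 7 not passing (4 higher and 5 lower alone), and the isocitrate lyase gene acu-3 was among 2 of 5 glyoxylate and gluconeogenesis genes with a lower difference at 4 h (-4.39, adjusted p = 0.0094).

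Over time on Avicel (no test; the 30 min and 2 h points are single libraries), cbh-1 stood at 119.15 FPKM at 30 min, at 118.5, 190.15 and 188.78 FPKM at 1 h, at 5010.4 FPKM at 2 h and at 186620, 86756 and 104220 FPKM at 4 h. Sugar transporters were already 5.91 above sucrose at 30 min as a median log2 difference, and 6.21, 7.20 and 7.32 at 1 h, 2 h and 4 h. The cellulase median went 2.97, 3.25, 7.22 and 10.06 at the same points, and that of the monooxygenase and dehydrogenase genes 0.46, 1.77, 4.96 and 9.65. At 1 h the single no-carbon library had a cellulase median of 3.60 and clr-2 at 139.75 FPKM, so that the early levels on Avicel cannot be separated from the loss of sucrose. The folding genes of the endoplasmic reticulum on Avicel had -0.05, 0.36, 0.25 and 1.77.

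**Figure D3:**
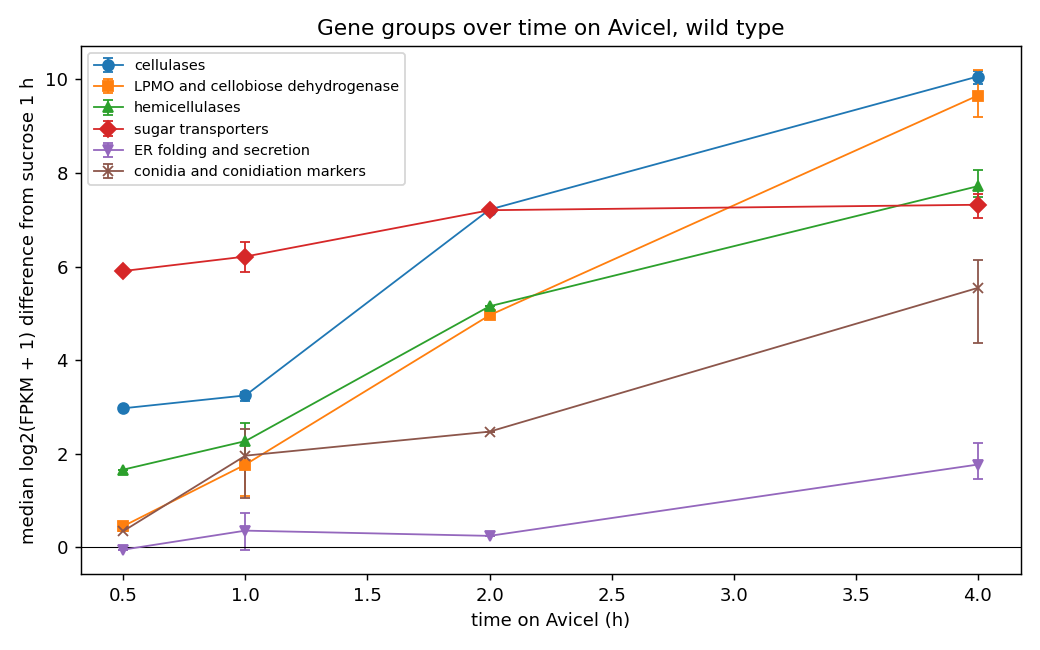
Median log2 difference from sucrose at 1 h for gene lists over the time on Avicel in wild type. Bars span the lowest and highest library.

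The deletion strains lack a transcription factor that is needed for growth on cellulose, which makes the deleted gene the first thing to read. In the clr-2 deletion strain clr-2 is listed at 0 in all 4 libraries. In the clr-1 deletion strain clr-1 stands at 6.13 FPKM on Avicel at 1 h, 11.01 on Avicel at 4 h, 12.99 on sucrose at 1 h and 23.1 on sucrose at 4 h, against wild-type means of 386, 802, 36.4 and 45.6 FPKM. The deposited values count a whole transcript model, so they do not show whether this remainder comes from the deleted reading frame. Each deletion group is 1 library with no check of replicates, and its tests assume that it varies as the wild-type libraries do.

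On Avicel at 4 h 8 of the 12 cellulase genes were lower than in wild type in each deletion strain. In the clr-1 deletion strain cbh-1 was at 168 FPKM and gh6-2 at 127 FPKM (log2 change from wild type -9.46, SE 0.70, adjusted p = 3.2e-06 and -9.31, SE 0.61, adjusted p = 1.2e-06); in the clr-2 deletion strain they were at 149 and 122 FPKM (-9.63, adjusted p = 2.1e-06 and -9.37, adjusted p = 8.0e-07). The dehydrogenase gene cdh-1 fell (log2 change -9.48 and -9.17, SE 0.41, adjusted p = 3.5e-08 and 2.7e-08), and the monooxygenase gene gh61-4 was listed at 0 in both. The clr-1 deletion lowered clr-2 to 15.1 FPKM (-6.34, SE 0.50, adjusted p = 5.0e-06), whereas in the clr-2 deletion strain clr-1 was at 506.5 FPKM and did not pass. The beta-glucosidase genes gh3-3 and gh1-1, chosen after their values were seen, did not pass in either strain and stood above their sucrose levels: gh3-3 was at 460.8 FPKM in the clr-1 and 3354 FPKM in the clr-2 deletion strain (2.50 and 2.79 FPKM on sucrose; wild type on Avicel 8732 ± 4587 FPKM), and gh1-1 at 750.8 and 2743 FPKM (54.1 and 20.4 FPKM on sucrose; wild type 42400 ± 8685 FPKM). Without the 36- and 40-base libraries gh1-1 was lower in both strains and gh3-3 in the clr-1 deletion strain, at an adjusted p under 0.05. The transporter gene cdt-1 fell less, to 852 FPKM (-4.51, SE 0.69, adjusted p = 0.0030) and 1517 FPKM (-3.67, adjusted p = 0.017), as did the acetylxylan esterase gene NCU05159, to 1828 FPKM (-4.16, SE 0.45, adjusted p = 1.2e-04) and 1325 FPKM (-4.62, adjusted p = 3.2e-05). With the clr-1 deletion 109 genes changed, 17 higher and 92 lower, and with the clr-2 deletion 87 changed, 9 higher and 78 lower; unadjusted p was under 0.05 for 598 and 374 genes, voom called 133 and 89, and the fit without the 36- and 40-base libraries 383 and 194. Higher in both were NCU01298 (3280 and 3210 FPKM against 56.9 ± 14.7; log2 change 5.86, adjusted p = 7.1e-06 and 5.83, adjusted p = 7.6e-06) and the pheromone receptor gene pre-2 (3.51, adjusted p = 1.5e-04 and 3.53, adjusted p = 1.2e-04). The mating type A gene matA-1 and the pheromone gene ccg-4 were listed at 0 in both strains. A difference in mating type, taken up under Other observations, could therefore account for pre-2 without an effect of the deletions. The 109 and 87 genes may hold others of this kind.

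By list, the clr-1 deletion lowered 8 of 12 cellulase genes on Avicel at 4 h (12 adjusted over the list alone; camera adjusted p = 1.6e-44), 9 of 14 monooxygenase and dehydrogenase genes (10 alone) and 7 of 19 hemicellulase genes (9 alone). The clr-2 deletion lowered 8 of 12 (11 alone; camera adjusted p = 1.5e-47), 9 of 14 (10 alone) and 8 of 19 (10 alone). Folding genes of the endoplasmic reticulum passed singly in 1 and 0 of 8 cases, and in 7 of 8 adjusted over the list alone in each strain (camera adjusted p = 4.1e-11 and 3.5e-11). With an estimated correlation camera gave the folding genes adjusted p = 0.021 and 0.020, and the cellulases adjusted p = 1.8e-04 and 1.4e-04. Of the sugar transporters only 1 of 13 was lower in each strain and 12 did not pass, and of the pectin genes 1 of 4 was lower. No gene of pentose metabolism, starch degradation or glycolysis passed, no conidiation marker did, and none of the light and clock, quinic acid cluster or housekeeping genes. The median pentose change was 0.33 and 0.47, but -0.22 and -0.16 without the 36- and 40-base libraries. The median log2 difference of the cellulases between Avicel and sucrose of the same strain was 2.14 and 3.05 in the clr-1 and clr-2 deletion strains, where it was not tested, and 10.102 in wild type. For the hemicellulases it was 5.67, 3.99 and 8.18, and for the sugar transporters 6.37, 6.10 and 7.86. Genes of the glyoxylate and gluconeogenesis list were higher as a group in the clr-1 deletion strain (camera adjusted p = 2.3e-04; adjusted p = 0.113 with an estimated correlation; 2 of 5 higher adjusted over the list alone). Of the 211 genes in the authors' cluster list, which the study chose on these samples and which is not independent evidence, 76 and 65 were lower and 0 higher.

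**Figure D4:**
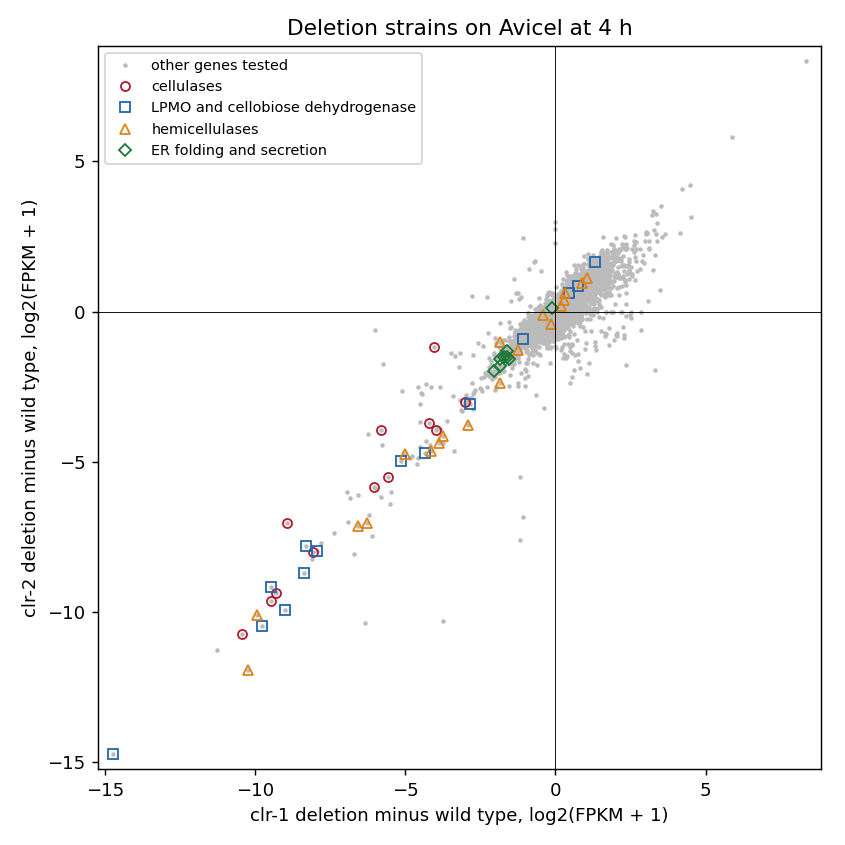
Log2 difference from wild type on Avicel at 4 h in the clr-2 deletion strain against that in the clr-1 deletion strain, per gene. Both axes use the same 3 wild-type libraries.

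The changes of the deletion strains on Avicel at 4 h were alike. Of 92 and 78 lower genes 70 were shared, against 0.83 for independent calls, and of 17 and 9 higher genes 8 were shared. A simulation without effects shared 0, which is no baseline, since it calls almost no gene, and part of the excess may come from the shared controls. The log2 changes over all genes correlate at r = 0.89, against 0.25 simulated without effects from the shared wild-type libraries, and their covariance is 0.71 against 0.10 simulated. The simulation gives every library the same spread and leaves out read length. Both deletion libraries have 50-base reads, whereas the shared wild-type replicate 1 library has 40-base reads. A difference they share for that reason would raise r without an effect of the deletions, so 0.25 may be too low a baseline. The strains may also share a mating type that wild type lacks (see Other observations), which could raise the shared calls and r as well. Of the 239 genes higher on Avicel than in both other media, 80 were lower with the clr-1 deletion and 67 with the clr-2 deletion, 62 of them in both, and the median log2 changes were -1.58 and -1.37. These genes were chosen as high in the same wild-type Avicel libraries that are the reference here, which by itself can push their changes downward.

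Whether the deletions change the response to Avicel was tested directly, as the difference between strains of the Avicel to sucrose change at 4 h. The clr-1 deletion changed the response of 41 genes, 1 upward and 40 downward, and the clr-2 deletion that of 39, 1 upward and 38 downward; 440 and 334 genes had an unadjusted p under 0.05, and voom called 28 (4 upward, 24 downward) and 16. The response of cbh-1 was smaller (log2 change -9.11, SE 0.99, adjusted p = 3.4e-04 and -8.84, adjusted p = 4.3e-04), as was that of cdh-1 (-8.27, SE 0.58, adjusted p = 1.7e-05 and -8.15, adjusted p = 2.1e-05). For cellulases the response of 6 of 12 was changed downward in each strain (11 and 9 adjusted over the list alone), for monooxygenase and dehydrogenase genes 7 of 14 (9 and 9), and for hemicellulases 4 and 5 of 19 (8 and 9). Without the wild-type sucrose 4 h replicate 1 library the clr-1 count was 67, and without all the 36- and 40-base libraries the counts were 596 and 332. They were 74 and 59 with a pseudocount of 10 and 22 and 21 with a pseudocount of 0.1.

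At 1 h on Avicel 1 gene passed with the clr-1 deletion and 5 with the clr-2 deletion, against 39 and 19 without the 36- and 40-base libraries. With the clr-1 deletion the gene was clr-1 itself (log2 change -5.70, SE 0.51, adjusted p = 3.2e-04), and clr-2, at 13.98 FPKM against 99.5 ± 26.7, did not pass; 321 genes had an unadjusted p under 0.05, voom called 4, and the count was 5 without the wild-type Avicel 1 h replicate 1 library. As groups cellulases (camera adjusted p = 0.0020; adjusted p = 0.345 with an estimated correlation) and sugar transporters (adjusted p = 0.0224; adjusted p = 0.345 with an estimated correlation) were lower and folding genes of the endoplasmic reticulum (adjusted p = 0.0020; adjusted p = 0.345 with an estimated correlation) and glycolysis genes (adjusted p = 0.0020; adjusted p = 0.345 with an estimated correlation) higher. With the clr-2 deletion 5 genes were lower: clr-2, NCU09968, NCU09969 and NCU11930, all listed at 0, and NCU02061 (-2.90, adjusted p = 0.031), which was chosen after its values were seen and did not pass without any 1 of the wild-type Avicel 1 h libraries; 56 genes had an unadjusted p under 0.05 and voom called 3. The folding genes were higher as a group (adjusted p = 2.4e-05), but adjusted p = 0.423 with an estimated correlation. The monooxygenase and dehydrogenase genes were lower as a group (adjusted p = 0.045; adjusted p = 0.423 with an estimated correlation).

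On sucrose at 4 h the cellulase genes are barely expressed. There 6 genes differed from wild type in the clr-1 deletion strain (5 higher, 1 lower) and 7 in the clr-2 deletion strain (3 higher, 4 lower). An unadjusted p under 0.05 was found for 756 and 532 genes, more than the 598 and 374 on Avicel at 4 h. With voom 5 (2 higher, 3 lower) and 12 were called, and without the 36- and 40-base libraries the counts were 1603 and 1077. An effect of the deletion cannot be told apart here from other differences of strain or library. The cell wall protein gene acw-12 was higher with the clr-1 deletion (3393 FPKM against 672 ± 277; log2 change 2.41, adjusted p = 0.048), and NCU07473 with both (1.87, adjusted p = 0.047 and 1.93, adjusted p = 0.020); neither passed for the clr-1 deletion after rescaling to the median of gene ratios (adjusted p = 0.099). NCU02061 was listed at 0 in both, against 20.9 ± 4.98 FPKM in wild type (adjusted p = 0.0014 and 3.4e-04). The clr-1 count depends on single libraries: 197 without the wild-type sucrose 4 h replicate 1 library, 1 without replicate 3, and 1 (0 higher, 1 lower) after rescaling to the median of gene ratios. With the clr-2 deletion the monooxygenase and dehydrogenase genes were lower as a group (camera adjusted p = 0.029; adjusted p = 0.839 with an estimated correlation). The clr-2 count was 16 without replicate 1, 14 without replicate 2 and 4 without replicate 3 of the same group. Set against each other on Avicel at 4 h, the deletion strains differed in 5 genes: clr-1 (11.01 FPKM in the clr-1 and 506.5 FPKM in the clr-2 deletion strain; log2 change -5.40, SE 0.62, adjusted p = 0.0017), and clr-2, NCU09968, NCU09969 and NCU11930, which are at 15.1, 83.2, 19.1 and 52.4 FPKM in the clr-1 deletion strain and listed at 0 in the clr-2 deletion strain. Only 29 genes had an unadjusted p under 0.05 there, and voom called 5 (3 higher, 2 lower). Camera called 4 lists there, and 0 with an estimated correlation. Glyoxylate and gluconeogenesis genes were higher in the clr-1 deletion strain (median log2 difference 1.45, adjusted p = 3.8e-06, adjusted p = 0.226 with an estimated correlation). Lower were the cellulases (median -0.068, adjusted p = 0.0071), the housekeeping genes (-0.35, adjusted p = 0.0163) and the authors' clusters (-0.082, adjusted p = 0.0018).

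The authors' own result tables for wild type at 4 h can be set beside these calls. For Avicel against sucrose their DESeq table calls 4547 genes, of which 4375 are tested here; 3995 of those are called here too, 3994 in the same direction. Their edgeR table calls 5028, 4772 tested here, 4144 called here and 4142 in the same direction. For Avicel against no carbon the numbers are 418, 403, 274 and 274 in the DESeq table and 781, 733, 324 and 324 in the edgeR table. These tables come from the same libraries and are not independent evidence.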

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

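The tests of depth, of the short-read library and of strain background below were chosen after seeing the result; the splits of libraries were planned. Each comparison of 6 wild-type libraries allows 10 splits into groups of 3, so the real split can be the highest of 10 at best, too few for a share under 0.05. It was the highest in each (value 1 of 10): Avicel against sucrose at 4 h had 5043 calls and at most 3 in another split, Avicel against no carbon 465 and 1, no carbon against sucrose 5456 and 0, Avicel against sucrose at 1 h 5348 and 6. For the 2684 genes whose response differed between 4 h and 1 h, 2 of 100 splits of the 12 libraries reached the real count, the real one and another with 2950. That other split places 5 of the 6 Avicel libraries on 1 side, so it holds the difference between the media itself. The splits shuffle medium and time together. A split that mixes media within a group puts their difference into the spread, so its low count is no baseline for the difference in time.

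The deletions changed the Avicel response of 41 genes (clr-1) and 39 genes (clr-2), tested as interactions, 40 and 38 of them downward, among them 6 of the 12 cellulase genes in each strain. Unequal depth or scaling is unlikely to explain the lower cellulase genes: 77 genes outside the lists, the 10 nearest to each cellulase in wild-type level (7.65 to 33103 FPKM, against 7.68 to 125860 FPKM for the cellulases), have median changes of 0.17 and 0.041, and the cellulases have -5.91 and -5.67. The match in level is loose, with a median of 2205 FPKM for the 77 genes and 9951 FPKM for the cellulases. The highest cellulases have no counterpart at their level. The short-read replicate 1 library is unlikely to explain them either, since 11 cellulase genes are lower without the 36- and 40-base libraries in the strain with fewer, against 8 with them. Strain background other than the deletion cannot be told apart from the deletion: on sucrose at 4 h the cellulase medians are -0.14 and -0.41, but low expression there leaves little room for a fall, and a deletion strain with the gene put back would be needed.

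In the single no-carbon library at 1 h, which no comparison uses, clr-2 stands at 139.75 FPKM, whereas the highest sucrose library at 1 h has 2.51 FPKM; Avicel at 1 h has 99.5 ± 26.7 FPKM (n = 3), so the early level of clr-2 is not particular to Avicel in these values. The conidiation markers in the same library are at a median of 4.36 log2 above sucrose at 1 h. Neither was tested, because 1 library has no replicate.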

How the results depend on the processing

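No gene called in a comparison was called in the opposite direction under another setting. Of 211 gene counts under another setting, 171 stayed within 1.5-fold, 11 were lower and 29 higher; of 70 list counts, 52, 15 and 3. Of 1308 values of named genes 30 lost and 8 gained a call, most of the lost ones of acw-12, NCU07473 and NCU02061. Where no reason is given the cause was not tested.

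The pseudocount moved small counts. With 0.1, calls for the clr-1 deletion were 2 on Avicel at 1 h and 17 on sucrose, for the clr-2 deletion 12 on sucrose, and the changes in response 22 and 21. With 10 they were 2, 0, 11, 74 and 59. A filter of 10 FPKM gave 3 for the clr-1 deletion on sucrose, rescaling 1 and the replicate block 1. No trend gave 2 for the clr-1 deletion on Avicel at 1 h and 11 for the clr-2 deletion on sucrose. The block is not backed by the check for no carbon (same-number correlations -0.31 to 0.45 with Avicel and -0.12 to -0.02 with sucrose; 2 and 0 of 6 libraries closest to their own number) and gave 490 and 5587 calls.

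Of the alternatives chosen after seeing the data, the fit without the 36- and 40-base libraries raised most counts: Avicel against no carbon 1136; clr-1 and clr-2 deletion 383 and 194 on Avicel at 4 h, 39 and 19 at 1 h, 1603 and 1077 on sucrose, 596 and 332 for the response; between the strains 10. A read-length covariate gave 2 for the clr-1 deletion on Avicel at 1 h, and 12 and 18 on sucrose. With voom the counts were 4 and 3 on Avicel at 1 h, 12 for the clr-2 deletion on sucrose and 16 for its response.

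Leaving out 1 library gave 4440 to 5114 calls for Avicel against sucrose at 4 h, 300 to 433 for Avicel against no carbon, 4896 to 5267 for no carbon against sucrose, 4831 to 5162 for Avicel against sucrose at 1 h and 2052 to 2795 for the 4 h against 1 h response. For the clr-1 and clr-2 deletions it gave 95 to 114 and 74 to 84 on Avicel at 4 h, 1 to 5 and 4 to 7 at 1 h, 1 to 197 and 4 to 16 on sucrose, and 37 to 67 and 35 to 43 for the response.

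Lists called depend on the assumed correlation. With an estimated correlation they were 6 for Avicel against sucrose at 4 h, 0 for no carbon against sucrose, 0 for Avicel against sucrose at 1 h, 4 for the 4 h against 1 h response, 0 for the clr-1 and 0 for the clr-2 deletion on Avicel at 1 h, 0 for the clr-2 deletion on sucrose and 0 between the strains. With fry, which tests a list for a change in a common direction and not against other genes, they were 15 for Avicel against sucrose at 1 h, 1 and 0 for the deletions on Avicel at 1 h, 0 for the clr-2 deletion on sucrose and 0 between the strains. For the clr-2 deletion, rescaling gave 1 on Avicel at 1 h and 0 on sucrose, and the block 1 on Avicel at 1 h. Without the 36- and 40-base libraries it had 4 there, and the clr-1 deletion on sucrose 1.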

Other observations

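The gene families of this part were chosen after seeing the results, and so were the tests of mating type, of genome change and of loss of clr-2 transcript; the tests of low depth were written before. Genes of amino acid synthesis were lower on Avicel and without carbon than on fresh sucrose. No library from before the shift shows whether they fell or rose on fresh sucrose. Of 59 such genes 55 were lower on Avicel than on sucrose at 4 h (median log2 change -3.003; camera adjusted p = 4.7e-19, adjusted p = 0.126 with an estimated correlation) and 55 without carbon (-3.16; adjusted p = 8.6e-21, adjusted p = 0.105 with an estimated correlation), and 38 on Avicel at 1 h. Between Avicel and no carbon at 4 h 4 were higher and 0 lower. All 18 genes for protein import into mitochondria were lower on Avicel and without carbon at 4 h, 17 of them on Avicel at 1 h (median -2.47 on Avicel at 4 h; camera adjusted p = 8.7e-11, adjusted p = 0.126 with an estimated correlation). Heat shock genes were lower in 8 of 10 cases in each medium at 4 h. Peroxisome genes were higher in 15 of 20 cases on Avicel at 1 h (median 1.13; adjusted p = 0.0015, adjusted p = 0.408 with an estimated correlation), but 2 were higher and 4 lower at 4 h. The family was not tested for a difference between the times. At 1 h 11 of 13 vacuolar ATPase genes were higher too, and 12 of 16 citric acid cycle genes lower.

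The mating type A gene matA-1 and the pheromone gene ccg-4, which is expressed in that mating type, are listed at 0 in the deletion libraries, whereas matA-1 is above 0 in 17 of 18 wild-type libraries. Deletion strains of the other mating type could explain this. The receptor gene pre-2 is above every wild-type library of the same medium and time in 8 of 8 deletion libraries. Only on Avicel at 4 h is the gap wide (194 and 198 FPKM against at most 20.6). On Avicel at 1 h it is 8.91 and 10.2 against at most 8.25 FPKM, and on sucrose 1.30 to 2.74 FPKM against 0. The other receptor gene, pre-1, is below all matched wild-type libraries only on sucrose at 1 h. On Avicel at 4 h pre-1 is at 20.7 and 23.0 FPKM, against 19.0, 218 and 248 FPKM in wild type. Loss of clr-2 transcript is unlikely, because wild type on sucrose has almost none and still has ccg-4 at 5.69 FPKM or more. Low depth of the deletion libraries is unlikely, since in 8 of 8 ccg-4 would hold at least 10 reads at the lowest wild-type level (lowest 41.1). Genotyping the mating type would settle it; the wild type then differs from the deletion strains by more than the deleted gene.

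In every clr-2 deletion library 3 further genes, NCU09968, NCU09969 and NCU11930, are listed at 0. In the clr-1 deletion strain they are above 0 but lower than in every wild-type library of the same medium and time, with NCU09968 at 59.0 to 112 FPKM against 125.59 to 328.1 FPKM over all wild-type libraries; no test was made of that difference as a pattern. A change in the clr-2 deletion strain's genome outside clr-2 stays open: NCU09968 and NCU09969 are neighbours on supercontig 6 (309679 to 313666 and 314113 to 320071), and 6e-04 of 10000 random triples hold neighbours, but this was computed after the neighbours had been seen, and NCU11930 lies on supercontig 2. Loss of clr-2 transcript is unlikely, as the lowest of the 3 in wild type on sucrose is 37.8 FPKM, and so is low depth of the clr-2 deletion libraries, since at least 761 reads would be expected. Genomic reads over both places would decide.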
